A study of Mus musculus with 25 samples.

How the data were processed

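H3K27me3 was profiled by CUT&RUN in 6 NPC libraries and by ChIP-seq in 12 MEF libraries, with 7 further ChIP-seq and input libraries, per the labels' protocols. These 7 were grouped as line A without Ezh2 from their titles, which name Ezh2 and do not state its loss. The H3K27me3 libraries of line A without Ezh2 carry a different name, so the 7 may come from cells with Ezh2 restored. The antibody was the H3K27me3 clone C36B11 of Cell Signaling Technology, per the labels. Samples were grouped from their titles or source names into 13 groups, 12 with 2 libraries and 1 (the input) with 1. The labels do not say whether replicates came from separate cultures, and no p value here measures the spread between libraries.

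The deposited files used here were 3 peak lists of 3 columns, the chromosome, start and end of each peak, with no header, score, fold or p value. They were given for the series as a whole and not per sample. The submitters' processing notes name Bowtie2 2.2.9, Picard, DESeq2, deepTools and MACS2 2.1.1.20160309 and the builds mm10 and dm6, with no role or order. The peak threshold, the control, the pooling of replicates and the libraries behind each list are not given in the sources used here. A line of MEF is named in its list by joining the names of its wild-type and Ezh2-deficient libraries. The Ezh2-deficient libraries may have entered as pooled data or as a control, or may be named for another reason. The lists hold no peak on a sex chromosome. Peaks did not overlap within a list, and the smallest gap between peaks was 4.0 times the smallest width in each list (709 and 177 bp in line B, 773 and 193 bp in line A, 1145 and 286 bp in NPC). No read count, coverage signal or total was analysed, so depth is unknown. Starts were read as 0-based, as the BED format has them, and are printed 1-based.

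Genes were the 20665 autosomal protein-coding records of a RefSeq table of assembly GRCm38.p6, the assembly of mm10, out of 21900 protein-coding records. The table gives the start and end of each gene with no strand, exon or transcript. The design, the gene lists and the first set of alternatives were fixed before the data were examined. The design took a promoter as 2 kb around the transcription start. In its place a gene was counted as having a peak where a peak lay within 2 kb of either end of its record, so a peak at the 3' end counts as well. All 328 symbols of the 14 gene lists matched the table, and 317 were tested, since 11 lie on the X chromosome. The lists were Hox clusters, neural progenitor genes, neuronal subtype transcription factors, mesenchymal and fibroblast genes, endoderm factors, mesoderm and muscle factors, the T-box, Irx and Pax families with 1 more homeobox family, Wnt ligands, cell cycle inhibitors, pluripotency genes, germline genes, Polycomb subunits, blood and endothelial genes and housekeeping genes. Some genes stand in more than 1 list.

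Overlap of peak lists was counted as at least 1 bp and compared with 1000 placements of the peaks at random on their own chromosomes between the first and last feature, one-sided. Placed peaks were free to overlap each other, and sequence that cannot be mapped was not masked, which lowers the random overlap. Location used as many placements, two-sided, and overlap by width used 100. Genes shared between lists and gene lists were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 42 tests of 14 lists in 3 peak lists, and over the 14 lists for each comparison between lists, at a threshold of 0.05. Width of shared and unshared peaks was compared by a permutation of the difference in medians with 100000 resamples, two-sided. Shares carry 95% exact binomial (Clopper-Pearson) intervals, and a count of 0 was given the limit of 3 counts. Intervals and limits cover counting error only, and peaks and genes are not replicates.

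The genes named were chosen by a rule fixed with the design. It took up to 4 members of each list with the longest peak coverage within 5 kb of the gene (here of either end), members on 1 side of a difference, and the 8 genes with the most covered length in each of 5 categories with 0 bp in the lists that lack them, leaving out predicted genes. It also took the 3 longest regions of each list after peaks less than 3 kb apart were joined, and Ezh2. Some list members that the rule takes are not reported here. Covered length counts both windows once where they overlap, so a gene has up to 20 kb. Cdkn2b, Pou5f1 and the gene families and Hox paralog groups were chosen after their values were seen.

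The scripts were tested on simulated data. With 0, 10 and 50% of 86235 simulated peaks copied from the other list, the overlap found was 17.7, 25.7 and 58.9%. The values expected were 17.7, 25.7 and 58.7%, from the copied share and the random overlap of the same run. At 0% this sets random placement against itself, and the simulated peaks were not clustered. Of 200 random lists of 25 genes, 9 were called at the threshold without adjustment. In 200 further lists, 18 of 25 members were taken from genes with a line A peak and the others from genes without one. All 200 were called. The counts were fixed and the same in each list, so this is no estimate of power. Alternatives from the first set were an overlap of at least 50% of the peak or of both peaks, circular shifts, peaks of 500 bp or more, joined peaks, windows of 1 and 5 kb and at least 500 bp covered. Those chosen after seeing the data were peaks at or above the median width, the 22403 widest peaks of each list, a peak at both ends of the gene, 50% of the gene record and 2 kb around it covered, and leaving out chromosome 7. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.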

Results

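H3K27me3, the histone mark that Polycomb repressive complex 2 (PRC2) places at silenced developmental genes, was profiled in 3 mouse cell systems in a study of transcriptional memory at Polycomb target genes. The 25 libraries formed 13 groups. Neural progenitor cells (NPC) derived from embryonic stem cells gave 6 CUT&RUN libraries, in which an antibody directs a nuclease to cut the marked chromatin out of permeabilized cells. These were 2 libraries each of untreated cells, of cells with the PRC2 inhibitors UNC1999 (2 uM) and A395 (4 uM), and of cells after washout of both compounds. Lines A and B of c-myc-immortalized mouse embryonic fibroblasts (MEF) gave 12 ChIP-seq libraries, 2 for each line as wild type, without Ezh2 (the methyltransferase of PRC2) and with Ezh2 restored. Ezh2 was restored by a retrovirus in line A and at the endogenous gene in line B, where the labels call its loss reversible. The other 7 libraries were 1 input and 2 each for RNA polymerase II, H3K4me3 and H3K36me3. They were grouped here as line A without Ezh2 from titles that name Ezh2 and do not state its loss. The H3K27me3 libraries of line A without Ezh2 carry a different name, so these 7 may come from cells with Ezh2 restored.

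The files analysed were 3 lists of H3K27me3 peaks, 1 per cell system, that hold peak positions and no heights. The depth behind each list is unknown. The name of each MEF list joins the wild-type and Ezh2-deficient libraries of that line, and the name of the NPC list gives no treatment. The part each library had in the peak calls is not given in the sources used here, so Ezh2 loss, rescue, inhibition and washout were not compared. Comparisons between lists had no replicate check. A peak in 1 list and not in another did not show that the signal differed, and the NPC and MEF lists differed in assay as well as in cell type.

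H3K27me3 peaks covered large, mostly intergenic parts of the autosomes in each system, with long blocks over Hoxb1, Pax5, Hmx1 and other genes. The line A list held 86235 peaks that covered 276.2 Mb (11.4% of the autosomes), the line B list 81972 peaks over 235.7 Mb (9.69%) and the NPC list 44807 peaks over 136.9 Mb (5.63%). Median peak width was 1420 bp in line A, 1123 bp in line B and 1458 bp in NPC, and the widest peak reached 166.4, 201.5 and 346.8 kb. All positions are given in the mouse build mm10. After peaks less than 3 kb apart were joined, the longest line A region spanned 410.2 kb on chromosome 8 (26170334 to 26580507) and contained no protein-coding gene record. The next spanned 385.8 kb on chromosome 11 (96361207 to 96747032) over Hoxb1 and Skap1, and the third 335.7 kb on chromosome 14 (30139799 to 30475480) over the calcium channel gene Cacna1d. The longest line B regions lay over Cntn2, Nfasc and Lrrn2 on chromosome 1 (132513720 to 132910635, 396.9 kb), over the B-cell factor gene Pax5 on chromosome 4 (44385566 to 44752945, 367.4 kb) and over Adra2c and the homeobox gene Hmx1 on chromosome 5 (35106552 to 35439550, 333.0 kb). The other fibroblast line covered at least 64.4% of each of these 6 regions, while NPC peaks covered between 0.453% and 54.8%. The longest NPC regions lay on chromosome 6 (99841919 to 100222005, 380.1 kb), on chromosome 7 over the heparan sulfate enzyme gene Hs3st4 (124110488 to 124423091, 312.6 kb) and on chromosome 9 (61422450 to 61721492, 299.0 kb). Line A peaks covered 69.3% of the chromosome 6 region, 0% of the Hs3st4 region and 73.8% of the chromosome 9 region, against 8.17%, 0% and 8.65% for line B.

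Peaks lay near gene ends more often than random placement gave. Of the peak length, 6.64% in line A, 8.01% in line B and 8.04% in NPC lay within 2 kb of an end of a protein-coding gene, against 5.96%, 5.80% and 6.32% for the same peaks placed at random on their chromosomes. Gene bodies held less than random placement gave (34.1% against 37.8% in line A, 31.7% against 37.7% in line B, 31.6% against 37.7% in NPC), and sequence outside genes held more (59.3%, 60.3% and 60.4%, against 56.3%, 56.5% and 56.0%). Each difference had p = 0.002 in a two-sided permutation test, the smallest that 1000 placements can give. Each peak was placed on its own, though many peaks of a list lie close together, so these p values overstate the evidence. Circular shifts were not run for location. Strand and exon structure were not used here, so the start and the end of a gene counted alike and exons were not told from introns.

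The fibroblast lines shared many of their H3K27me3 regions, with the share depending on the overlap asked for. Of the line A peaks, 41002 (47.5%, 95% exact binomial interval 47.2 to 47.9%) overlapped a line B peak by at least 1 bp, 3.02 times the 15.7% under random placement. Of the line B peaks, 41548 (50.7%, interval 50.3 to 51.0%) overlapped a line A peak, 2.98 times the random 17.0%. Where at least 50% of both peaks had to be shared, 12.2% of the line A peaks met a line B peak, 7.13 times the random 1.71%. The share rose with width, from 30.2% in the narrowest 25% of line A peaks to 71.6% in the widest 25%, and random placement rose with it from 11.1% to 23.0%, so that the ratio to random lay between 2.72 and 3.19. For line B peaks in line A the ratio rose from 2.52 in the narrowest 25% to 3.23 in the widest 25%. Shared line A peaks had a median width of 2345 bp against 959 bp for unshared ones, and in line B the medians were 1944 and 744 bp (permutation test of the difference in medians, two-sided, p = 1e-05, the smallest that 100000 resamples can give). Wider peaks overlap more by chance too, which this test does not take out. Both overlaps exceeded all 1000 placements (permutation test, one-sided, p = 0.001, the smallest possible). Peaks are not replicates, and the intervals cover counting error only.

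At the level of genes, 5919 of 20665 autosomal protein-coding genes had a line A peak within 2 kb of either end, 6139 had a line B peak and 4477 had both, where 1758 would be shared by independent lists (odds ratio 24.4, 95% interval 22.6 to 26.4). An NPC peak stood near 4384 genes, of which 2881 were shared with line A (odds ratio 8.36, interval 7.76 to 9.0) and 2730 with line B (odds ratio 6.23, interval 5.80 to 6.70). In all 3 lists stood 2306 genes. Ranked by covered length within 5 kb of their ends, the first 8 of these were regulators of neural, kidney and skeletal development and a sodium channel subunit. Isl1 (NCBI gene 16392, chromosome 13, 116298270 to 116309688), a factor of motor neurons and cardiac progenitors, and Prdm12 (gene 381359, chromosome 2, 31635026 to 31655795), a factor of pain-sensing neurons, were covered over the full 20 kb in each list. Pax2, a kidney and eye regulator, was covered over 20 kb in both MEF lines and 19.3 kb in NPC, and Pax1, of the developing vertebrae, over 19.2 kb in line A and 20 kb in the others. The hypothalamic factor Otp was covered over its whole 19.5 kb window in each list, and Prdm13, Hmx1 and the sodium channel subunit gene Scn4b over at least 18.6 kb in each list. Fisher's exact test gave p values below the smallest number the software can hold for each pair, so only the odds ratios are given. Neighbouring genes can share a peak and are not independent.

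Genes for transcription factors of other lineages carried H3K27me3 peaks in fibroblasts far more often than other genes. Of 26 neuronal subtype transcription factor genes, 23 had a peak in line A and 25 in line B (88.5% and 96.2%, against 28.6% and 29.6% of the other genes, Fisher's exact test, adjusted p = 6.6e-09 and 5.0e-11). Isl1, Lhx5 (a factor of spinal and forebrain neurons), Neurod2 (neuronal differentiation) and Evx2 (spinal interneurons) were covered over at least 14.2 kb in both lines. Of 18 endoderm transcription factor genes, 17 had a peak in each line (94.4%, adjusted p = 8.0e-08 and 9.8e-08), among them Nkx2-1 of lung and thyroid, Onecut1 and Hnf4a of liver, and the intestinal factor Cdx2. Mesoderm and muscle factors had a peak at 21 of 25 genes in line A and 18 in line B (adjusted p = 9.8e-08 and 5.0e-05), with Pax2, and Nkx2-5 and Gata5 of the heart, among the most covered. Of 22 further genes of the T-box, Irx and Pax families and 1 more homeobox family, 17 and 18 had a peak (adjusted p = 1.4e-05 and 3.3e-06), led by Pax1, Six3, Tbx21 and Irx4. Of the 19 Wnt ligand genes, 14 and 17 had one (adjusted p = 0.00018 and 5.7e-07), with Wnt3a, Wnt10a, Wnt7a and Wnt7b covered most. Neural progenitor genes had a peak at 18 of 24 members in line A and 21 in line B (adjusted p = 1.4e-05 and 8.0e-08). Lhx2 was covered over 20 kb and 18.6 kb, Nkx2-2 over 18.5 and 14.6 kb, and Pou3f2 over its whole window of 16.3 kb in both lines.

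**Figure D1:**
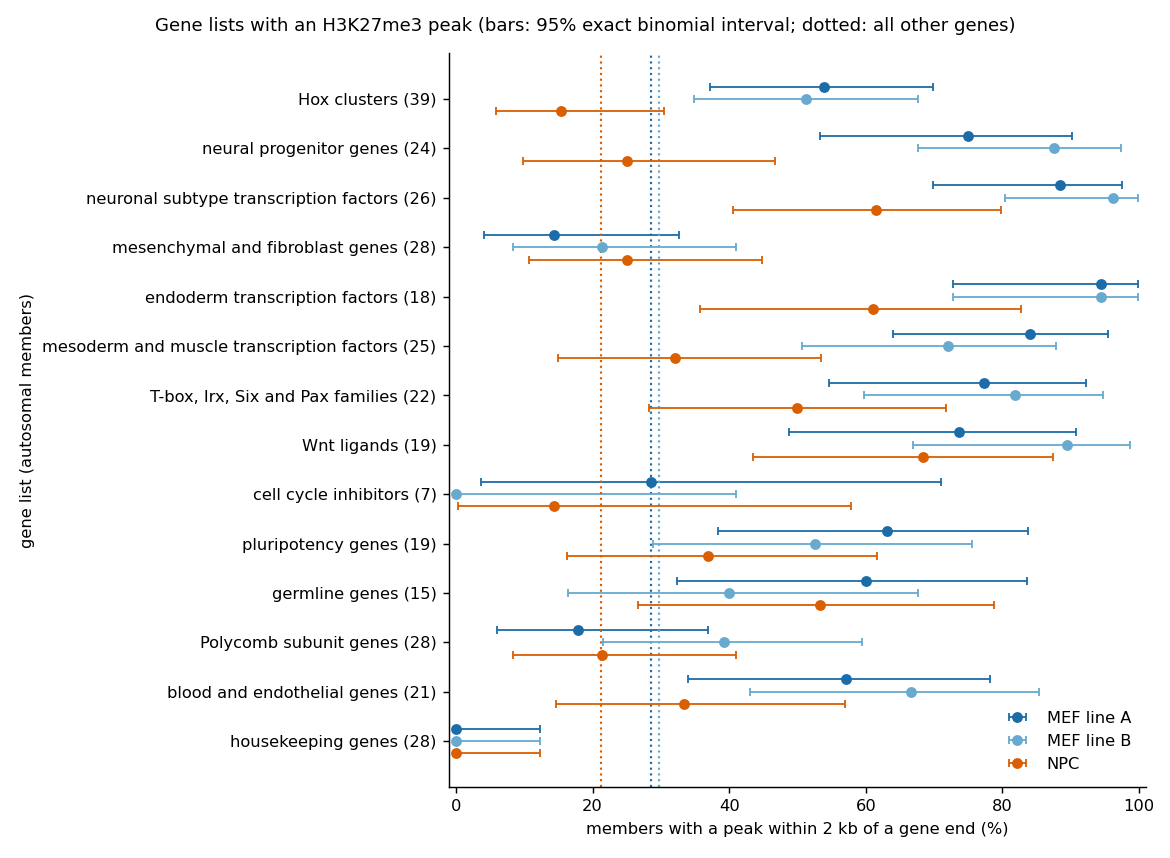
Share of the members of 14 gene lists with an H3K27me3 peak within 2 kb of an end of the gene (horizontal axis, percent), for the MEF line A, MEF line B and NPC peak lists, with 95% exact binomial intervals as bars and the share of all other genes as dotted lines. Developmental transcription factor lists lie to the right of the dotted lines in both MEF lines, and the 28 housekeeping genes lie at 0% in each list.

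Blood and endothelial genes had a peak at 12 of 21 members in line A and 14 in line B (Fisher's exact test, adjusted p = 0.011 and 0.0012), with the T-cell receptor subunit gene Cd3e, Lmo2, Ikzf1 and the VEGF receptor gene Kdr covered most. Pluripotency genes had one at 12 and 10 of 19 (adjusted p = 0.0038 and 0.065), led by Sall4, Fgf4 (on chromosome 7), Tfcp2l1 and Prdm14, and Pou5f1 had a peak in both MEF lines. Germline genes had one at 9 and 6 of 15 (adjusted p = 0.028 and 0.48), led by Mov10l1, Dazl, Tdrd1 and Asz1. The line A call for the germline list was lost within 1 kb of a gene end and without chromosome 7, among others (adjusted p between 0.0050 and 0.30 over 8 alternatives), and that for the pluripotency list within 5 kb, among others (0.0040 to 0.19). The blood and endothelial call was lost in line A within 5 kb and with the same number of widest peaks (0.0021 to 0.068), and in line B with 50% of the gene record covered (0.00034 to 0.23). Mesenchymal and fibroblast genes had a peak at 4 of 28 members in line A and 6 in line B (14.3% and 21.4%, adjusted p = 0.15 and 0.48). Cell cycle inhibitor genes had a peak at 2 of 7 members in line A and 0 in line B, which allows a share of up to 42.9%, and neither count passed the test (adjusted p = 1 and 0.16). Cdkn1c (7.98 kb, on chromosome 7, which line B peaks covered least) and Cdkn1a (5.73 kb) were covered in line A, while Cdkn2a and Cdkn2b, whose products restrain division in ageing fibroblasts, had 0 bp covered within 5 kb in each of the 3 lists. Polycomb subunit genes had a peak at 5 and 11 of 28 members (Fisher's exact test, adjusted p = 0.37 in both). Epop, Cbx2, Pcgf5 and Pcgf1 led by covered length, though Epop, Pcgf5 and Pcgf1 had a peak within 2 kb in line B and not in line A. Ezh2 itself, the gene lost in the Ezh2-deficient MEF libraries, had 0 bp covered within 5 kb of its ends in each list. Housekeeping genes had 0 of 28 in each line, which allows a share of up to 10.7% (adjusted p = 0.00045 and 0.00024). That call was lost where a peak at both ends of the gene (adjusted p = 0.052 and 0.075) or 50% of the record covered (0.18 in both) was required. In line A 10 of 14 lists lay above the other genes and 1 below, and in line B 8 lay above and 1 below. Benjamini-Hochberg adjustment ran over the 42 tests of 14 lists in 3 peak lists.

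In the Hox clusters, whose genes set position along the body axis, posterior genes (paralog groups 9 to 13) had a peak more often than anterior ones. The Hoxb cluster departed from this in both MEF lines, where anterior genes had peaks as well. Of 39 Hox genes, 21 had a peak in line A (53.8%, interval 37.2 to 69.9%), 20 in line B (51.3%, interval 34.8 to 67.6%) and 6 in NPC (15.4%, interval 5.86 to 30.5%). Among the 16 genes of paralog groups 9 to 13, 15 had a peak in line A, 11 in line B and 6 in NPC. Among the 23 genes of groups 1 to 8, the counts were 6, 9 and 0. All 6 of line A lay in the Hoxb cluster, as did those of line B except Hoxd1. At the Hoxb cluster on chromosome 11 (96194316 to 96368254), line A peaks covered 71.3%, line B peaks 96.8% and NPC peaks 10.4%. There Hoxb6 (18.8 kb) and Hoxb8 (15.9 kb) were covered over their whole windows in both MEF lines and over 0 kb in NPC. At the Hoxa cluster on chromosome 6 (52155367 to 52260880), line A peaks covered 34.7% of the cluster, from Hoxa9 to Hoxa13, and line B peaks covered 0%. Only Hoxa13 had a nearby peak in line B and NPC. At the Hoxc cluster on chromosome 15 (102921131 to 103036856), coverage was 46.3% in line A, 27.6% in line B and 19.3% in NPC, with Hoxc13 covered over its whole 17.7 kb window in each. At the Hoxd cluster on chromosome 2 (74668225 to 74765142), it was 26.5%, 35.6% and 0%, and Hoxd11 was covered over 16.5, 17.5 and 0 kb. Against all other genes, the Hox list lay above in line A (Fisher's exact test, adjusted p = 0.0024) and line B (0.0086), and not in NPC (0.50). In line B the call was lost within 5 kb of a gene end (adjusted p = 0.11, with 2.9e-07 to 0.11 over 8 alternatives). Genes of a cluster share peaks, so these p values overstate the evidence.

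**Figure D2:**
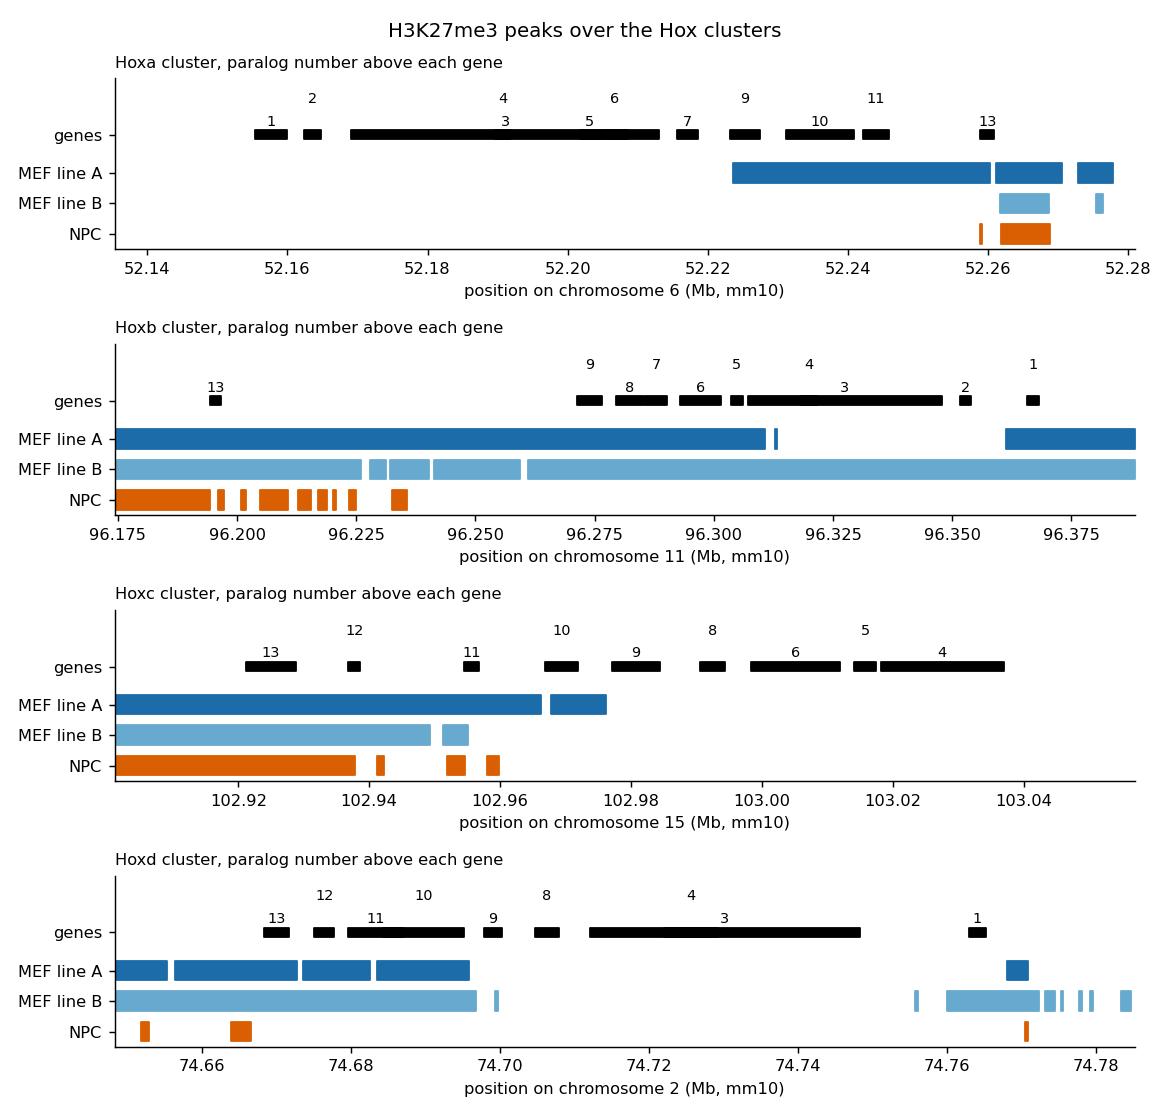
H3K27me3 peaks (bars) over the Hoxa, Hoxb, Hoxc and Hoxd clusters with 20 kb on either side, for MEF line A, MEF line B and NPC, with gene records in black and the paralog number above each (horizontal axis, mm10 position in Mb). Line A peaks run from Hoxa9 to Hoxa13, where line B peaks cover 0% of the cluster, and both MEF lines but not NPC are covered over Hoxb6 to Hoxb9.

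NPC shared many H3K27me3 regions with fibroblasts, among them regions at neuronal subtype factor, endoderm factor and Wnt ligand genes. Of the NPC peaks, 20523 (45.8%, interval 45.3 to 46.3%) overlapped a line A peak, 2.62 times the random 17.5%, and 17144 (38.3%, interval 37.8 to 38.7%) overlapped a line B peak, 2.57 times the random 14.9%. Where at least 50% of both peaks had to be shared, the shares were 10.1% with line A and 7.42% with line B, 4.95 and 4.47 times random. Both lay above all 1000 placements (permutation test, one-sided, p = 0.001). In the other direction 23.9% of line A and 20.9% of line B peaks overlapped an NPC peak, against 9.92% and 9.02% under random placement. NPC peaks shared with either MEF line had a median width of 1876 bp against 1137 bp for the rest (permutation test, two-sided, p = 1e-05). Wider peaks overlap more by chance as well, and the overlap of NPC with line A lay between 2.49 and 2.74 times the random one in 4 groups of NPC peaks by width, with no steady rise. The lists above the other genes in NPC numbered 5 of 14. These were neuronal subtype factors (16 of 26, Fisher's exact test, adjusted p = 3.7e-05), Wnt ligands (13 of 19, adjusted p = 4.5e-05), endoderm factors (11 of 18, adjusted p = 0.00068), the list of T-box, Irx and Pax families and 1 more homeobox family (11 of 22, adjusted p = 0.0050) and germline genes (8 of 15, adjusted p = 0.011). Of these, the endoderm, Wnt and germline calls were lost when a peak was required at both ends of the gene (adjusted p = 0.066, 0.73 and 0.72). Over 8 alternatives these ranged from 0.00019 to 0.26 for endoderm, 6.2e-05 to 0.73 for Wnt and 0.0044 to 0.72 for germline genes. Neural progenitor genes had a peak at 6 of 24 members (25% against 21.2% of other genes, adjusted p = 0.69), mesoderm and muscle factors at 8 of 25 (0.29), mesenchymal genes at 7 of 28 (0.69), pluripotency genes at 7 of 19 (0.22), blood and endothelial genes at 7 of 21 (0.25), Polycomb subunits at 6 of 28 (1), cell cycle inhibitors at 1 of 7 (1) and housekeeping genes at 0 of 28 (0.0039, below the other genes, and 0.37 where a peak at both ends was required).

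Set against each other, 2171 genes had a peak in both MEF lines and not in NPC, and 1079 had one in NPC and in neither MEF line. Of the 24 neural progenitor genes, 13 lay on the MEF side and 0 on the NPC side, including Olig1, Olig2, Pax6, Nkx2-2, Pou3f2, Fabp7 and Nes, the gene of the progenitor filament nestin. Where at least 500 bp had to be covered, 10 lay on the MEF side and 0 on the NPC side. Mesenchymal and fibroblast genes lay 0 on the MEF side and 4 on the NPC side, these being Snai2, Pdgfrb (10.4 kb covered in NPC), the fibronectin gene Fn1 and Fbln2. Hox genes lay 10 on the MEF side and 0 on the NPC side. With 66.8% of all these genes on the MEF side, 0 of 14 lists passed the adjusted test. The neural progenitor list had p = 0.0068 (adjusted 0.085), the mesenchymal list p = 0.012 (adjusted 0.085) and the Hox list p = 0.037 (adjusted 0.17), and these were the 3 lists with an unadjusted p under 0.05 (Fisher's exact test, two-sided). With the 22403 widest peaks of each list, an alternative chosen after seeing the data, the Hox (10 against 0, adjusted p = 0.016), neural progenitor (11 against 0, adjusted p = 0.016) and neuronal subtype lists (9 against 0, adjusted p = 0.021) passed, and within 5 kb of a gene end the mesenchymal list passed (0 against 5, adjusted p = 0.042). Over all 8 alternatives the adjusted p ranged from 0.016 to 0.34 for Hox, 0.016 to 0.32 for neural progenitor, 0.021 to 0.47 for neuronal subtype and 0.042 to 0.89 for mesenchymal genes.

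The genes most covered within 5 kb of their ends in both MEF lines, with 0 bp in NPC in those windows, included Otx2, a regulator of forebrain development (gene 18424, chromosome 14, 48656781 to 48667644), the potassium channel gene Kcnk1 and Sertm1, each covered over 20 kb in both lines. Cardiac myosin gene Myh7 (20 kb in line A and 19.2 kb in line B), Prkcq, a kinase of T cells (19.1 and 20 kb), the blood cell repressor gene Gfi1 (19.2 kb in both), the transporter gene Slc17a2 (19.2 and 19.1 kb) and the adrenergic receptor gene Adra1a (18.02 and 20 kb) followed. In NPC, with 0 bp within 5 kb of the gene ends in either MEF line, Adamtsl3, the bHLH factor gene Atoh8 (gene 71093, chromosome 6, 72206174 to 72235780) and the B-cell coactivator gene Pou2af1 were covered over 20 kb, Lrrc75b over 19.9 kb, the milk casein gene Csn1s2a over 18.5 kb, the aryl hydrocarbon receptor gene Ahr over 17.6 kb, the sulfatase gene Arsi over 17.5 kb and Ovch2 over 17.0 kb. Adamtsl3 and Ovch2 lie on chromosome 7, which held 324 of the 1079 genes of the NPC side (30.0%) and 43 of the 2171 of the MEF side (1.98%), against 9.82% of all genes.

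Of the genes near which a single fibroblast line had a peak, Hoxa10 in line A and Zic4 in line B were among the most covered. A peak in line A and not in line B stood near 1442 genes, and the reverse near 1662. Covered within 5 kb of the gene ends in line A, with 0 bp in those windows in line B and NPC, were Hoxa10 (19.7 kb, gene 15395, chromosome 6, 52231197 to 52240854), the glycosyltransferase gene Galnt18 (19.4 kb), the RNA-binding protein gene Celf2 (19.1 kb), the bHLH-PAS factor gene Arnt2 (18.8 kb), Alkal1 (18.3 kb), Smgc (18.04 kb), Arfgef3 (17.7 kb) and Slc25a13 (17.2 kb). Covered in the same windows in line B, with 0 bp there in line A and NPC, were the adjacent zinc finger factor genes Zic4 (20 kb, gene 22774, chromosome 9, 91365631 to 91389351) and Zic1 (17.7 kb), Trim9 (20 kb), Adam28 (19.1 kb), the nuclear receptor gene Nr2f1 (18.9 kb), Ppp2r2b (18.5 kb), the muscle gene Myoz2 (18.1 kb) and Pcp4l1 (17.4 kb). Among the fixed lists, Meox1 was covered over 16.0 kb in line B and 0 kb in line A, and Tbx18 over 15.1 kb in line A and 0 kb in line B. Polycomb subunit genes lay 0 on the line A side and 6 on the line B side (Cbx8, Phc1, Kdm6b, Epop, Pcgf1 and Pcgf5; Fisher's exact test, p = 0.033, adjusted 0.47), the single list with an unadjusted p under 0.05, and 0 of 14 lists passed the adjusted test. Within 5 kb of a gene end this list lay 2 against 2 (Fisher's exact test, p = 1, with 0.033 to 1 over 8 alternatives). Galnt18 and Arnt2 lie on chromosome 7, which held 220 of the 1442 line A genes (15.3%) and 67 of the 1662 line B genes (4.03%).

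Chromosome 7 set the lists apart more than any other autosome. NPC peaks covered 14.9% of chromosome 7 (21.6 of 145.3 Mb), while the next most covered chromosome in NPC, chromosome 9, reached 8.0%. Line B peaks covered 3.54% (5.15 Mb) and line A peaks 10.4% (15.1 Mb). Of all peaks of a list, chromosome 7 held 13.4% in NPC (exact binomial interval 13.1 to 13.7%), 5.71% in line A (interval 5.55 to 5.86%) and 3.09% in line B (interval 2.98 to 3.21%), with 5.98% of the autosomal length. The ratio of line B to line A coverage was 0.341 on chromosome 7 and between 0.659 and 1.22 on the other 18 autosomes, and that of NPC to line A was 1.43 against 0.280 to 0.677. Chromosome 19 was the most covered in both MEF lines (17.4% in line A and 13.1% in line B). Without chromosome 7, 48.8% of line A peaks overlapped a line B peak and 47.4% of NPC peaks overlapped a line A peak.

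**Figure D3:**
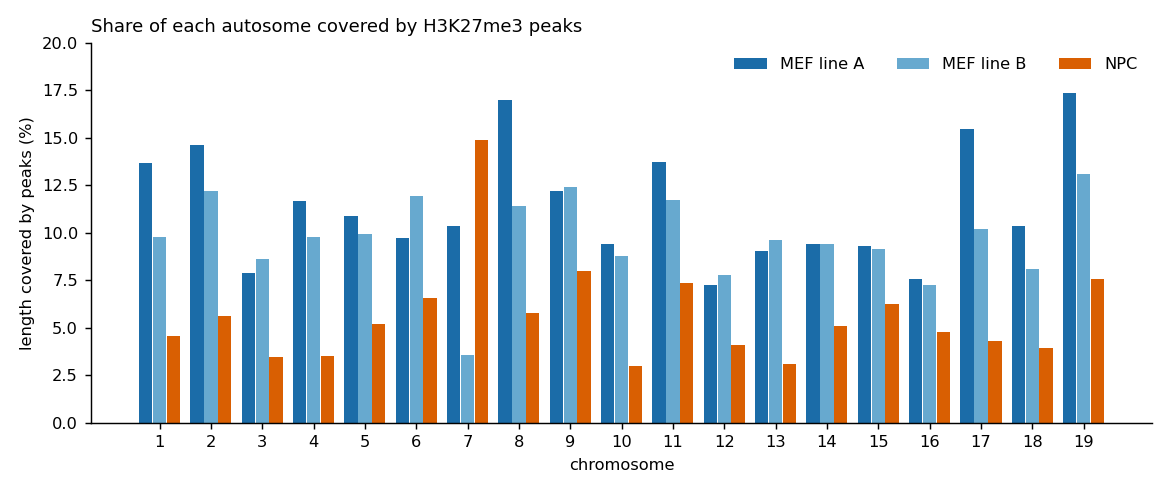
Share of the length of each autosome covered by H3K27me3 peaks (vertical axis, percent) in MEF line A, MEF line B and NPC, 1 bar per peak list and no replicates. On chromosome 7 the NPC bar stands at 14.9% and the line B bar at 3.54%, the highest NPC value and the lowest line B value.

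**Figure D4:**
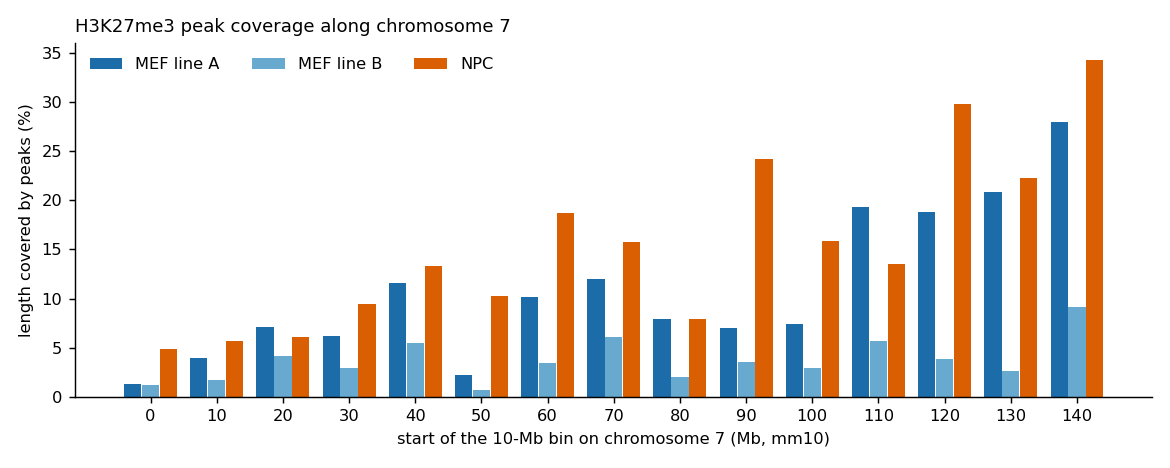
Share of each 10-Mb bin of chromosome 7 covered by H3K27me3 peaks (vertical axis, percent) in MEF line A, MEF line B and NPC, by start of the bin in Mb (horizontal axis, mm10). In 14 of the 15 bins the ratio of line B to line A lies below the median bin of the other chromosomes, and in all 15 the ratio of NPC to mean MEF coverage lies above it.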

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

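The alternatives with a peak at both ends, 50% of the gene record covered, peaks at or above the median width, the same number of widest peaks and no chromosome 7 were chosen after seeing the data. Peak overlaps, the odds ratios of shared genes and location kept their direction and their side of the threshold under every alternative run on them, but the share of line A peaks in line B moved from 47.5% to 35.0% with 50% of the peak covered and to 12.2% with 50% of both, and that of NPC peaks in line A from 45.8% to 35.9% and 10.1%. Joining peaks cannot change a gene call and is left out of the next counts. A change of direction in a list test that passed in neither setting was counted as kept. Of 336 list tests under 8 alternatives, 311 kept their side of the threshold, 23 lost and 1 gained the call. The other one, germline genes in NPC, went from above the other genes to 0 members when a peak at both ends was required. That rule left 2843 genes in line A, 2699 in line B and 1485 in NPC, with 1771 shared by the MEF lines, 860 by line A and NPC and 731 by line B and NPC. Coverage of 50% of the record left 2156, 2068 and 878 genes, with 1285, 467 and 391 shared. The same number of widest peaks left 3731 genes in line A, with 1731 shared by line A and NPC, 1723 by line B and NPC and 2575 by the MEF lines. Fewer genes follow from how these alternatives were built. Lists below the other genes went from 1 to 0 in each of the 3 peak lists with a peak at both ends and with 50% of the record covered, and to 2 in line A within 5 kb. Lists above the other genes in NPC fell from 5 to 2 and 3 under those alternatives. Between MEF and NPC, 1 list passed within 5 kb and 3 with the same number of widest peaks, against 0. For these list counts the cause was not tested. Joining left 38821 line A and 38018 line B regions. The share of peaks on chromosome 7 moved to 5.87% in line A, 2.86% in line B and 14.9% in NPC at or above the median width, and to 2.63% in line B and 14.9% in NPC with the same number of widest peaks (the cause was not tested). Alternatives by score were not run because the lists hold none, nor was that by any transcript start, and keeping the autosomes alone removed no peak. Replicates were not left out in turn because no list is given per replicate. No paired analysis was possible because the columns carry no replicate. Unknown depth limits what a missing peak shows.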

Other observations

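The family tests and the tests on chromosome 7 and olfactory genes were chosen after the results were seen, except that the bounds of 50% and 75% for complete loss in line B were written before its value. Beyond the fixed lists, 98 gene families (symbols with the same letters before the first digit, 20 or more autosomal genes) were tested in each peak list, with adjustment over 294 tests. Of these tests 89 passed, and a selection of families is given here. Keratin genes (Krt), structural genes of epithelia, had a peak at 52 of 53 members in line A, 36 in line B and 44 in NPC (Fisher's exact test, adjusted p = 5.6e-25, 5.7e-07 and 1.1e-19). Solute carrier genes (Slc) had one at 157 of 362 members in line A (43.4% against 28.4% of other genes, adjusted p = 8.2e-08) and 154 in line B (adjusted p = 5.4e-06), and at 87 in NPC, which did not pass (adjusted p = 0.34). Fibroblast growth factor genes (Fgf) had one at 14 of 20 members in each list (adjusted p = 0.0016 in line A, 0.0022 in line B and 8.6e-05 in NPC). Kallikrein genes (Klk), which all lie on chromosome 7, had one at 17 of 26 members in line A and NPC and 7 in line B (adjusted p = 0.0013, 3.6e-05 and 0.92). Translation initiation factor genes (Eif) had one at 2 of 53 members in line A and 3 each in line B and NPC (adjusted p = 0.00012, 0.00041 and 0.019, below the other genes). Zinc finger genes (Zfp) had a peak at 58 of 388 members in line A, 70 in line B and 54 in NPC (adjusted p = 9.0e-09, 4.5e-06 and 0.0024, below the other genes). Between NPC alone and both MEF lines without NPC, 5 of 98 families passed: Olfr, the vomeronasal receptors (Vmn, 32 against 6, adjusted p = 4.8e-09), Serpina (8 against 0, 0.0047) and taste receptors (Tas, 8 against 1, 0.023) on the NPC side, and Slc (14 against 67, 0.034) on the MEF side. Vmn lay below other genes in both MEF lines (36 and 39 of 354, Fisher's exact test, adjusted p = 1.9e-15 and 2.1e-15). In NPC 68 Vmn genes had a peak, which did not pass (adjusted p = 0.58). The place of Vmn on the NPC side thus goes with a lack of MEF peaks, since the NPC share of Vmn did not lie above that of other genes. Tas had 2, 3 and 9 of 38 and Serpina 0, 7 and 9 of 23 in line A, line B and NPC. Neither passed in NPC (adjusted p = 0.83 and 0.11). Vmn, Serpina, Tas and Slc were not retested without chromosome 7. Family members lie in clusters that share peaks, so these p values overstate the evidence.

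Line B peaks covered 3.54% of chromosome 7 against 10.4% for line A. A few deviating regions are argued against, since 14 of the 15 bins of 10 Mb lay below the median bin of the other chromosomes in the ratio of line B to line A (0.397 in the median bin of chromosome 7 against 0.898). Complete loss of the mark is argued against for the 127 chromosome 7 genes with 50% of their record covered in line A. The bound set for it was a share under 50%, and 96 had a line B peak (75.6%, exact binomial interval 67.2 to 82.8%, against 89.7% elsewhere). Strictly, complete loss allows no line B peak, so this bound was lenient and says nothing about partial loss. The higher bound of 75% was not passed by more than the interval, and the choice to decide by the lower bound was made after the value was seen. Of the 348 less covered genes, 45.4% had a line B peak (interval 40.1 to 50.8%, against 70.3% elsewhere). The interval holds the 50%, so the bound set for these genes decides nothing. Complete loss from all of them is argued against, since it allows no line B peak there. Loss from a part of these genes stays open. A factor acting on the whole of chromosome 7 in the line B list, such as fewer copies of it or a weaker signal along it, stays open. It was not tested apart from the pattern. Peaks there were the most narrowed (rank 1 of 19, width ratio 0.673 against 0.719 or more elsewhere), but width is part of covered length. Copy number and a partial loss of H3K27me3 stay open as well, since reads, those of the line A input among them, were not analysed here. Beyond complete loss of the mark, no biological explanation was tested.

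NPC peaks covered 14.9% of chromosome 7, the opposite deviation. All 15 bins of 10 Mb lay above the median bin of the other chromosomes in the ratio of NPC to mean MEF coverage (lowest 1.08, against a median of 0.467 elsewhere), which argues against a few regions. That mean includes line B, itself low on chromosome 7, so this test is not independent of the line B pattern. Against line A alone, the ratio for the whole of chromosome 7 was 1.43, and 0.677 or less on the other autosomes. Clusters of olfactory receptor genes, of which chromosome 7 holds 239, are argued against as the cause, since the 12 bins with fewer than 10 of them were covered at 14.5%, above the 8.0% of chromosome 9. A factor acting on the whole of chromosome 7 in the NPC list, such as additional copies in these cells, stays open and was not tested apart from the pattern: NPC peaks there were the widest (rank 1 of 19, median 1700 bp against 1548 bp or less), but width is part of covered length. Copy number, the assay and the cell type stay open, and no biological explanation was tested.

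Olfactory receptor genes (Olfr) lay on the NPC side of the difference between NPC and MEF, with 151 marked in NPC and neither MEF line and 57 in both MEF lines and not NPC, against 928 and 2114 other genes (Fisher's exact test, odds ratio 0.166, p = 2.9e-33, adjusted over 98 families 2.8e-31). Of the 151, 98 lie on chromosome 7, where 119 of 239 Olfr genes (49.8%) had an NPC peak. The chromosome 7 excess of the NPC list is argued against as the whole cause, since outside chromosome 7 the counts were 53 and 57, against 702 and 2071 other genes (Fisher's exact test, odds ratio 0.365, p = 6.4e-07). There 19.3% of Olfr genes had an NPC peak, 18.7% a line A peak and 22.9% a line B peak, so the NPC share did not exceed both MEF shares. On all autosomes the shares were 25.9%, 16.5% and 19.2%, against 20.9%, 29.3% and 30.3% of other genes. Olfr genes thus lay below the other genes in both MEF lists, and their place on the NPC side is in part a lack of MEF peaks. Outside chromosome 7 an NPC peak stood near 167 of 865 Olfr genes and near 3674 of all 18635 genes. Olfr genes thus showed no NPC excess there, and their place on the NPC side outside chromosome 7 goes with the lack of MEF peaks. Olfr genes lie in clusters that share peaks, so these p values overstate the evidence. Reads shared between near-identical receptor genes and the difference in assay may add to these differences and were not tested here, since reads were not analysed.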
